A study of Mus musculus with 6 samples.

How the data were processed

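RNA sequencing of cultured mouse granulosa cells was analysed in 6 libraries, 3 from untreated cells and 3 from cells given polystyrene particles (PS-MP). Per the labels' protocols, cells came from ovaries of 21-day-old ICR mice, adhered for 12 h and were kept with particles of 100 nm at 0 or 750 µg/mL for 24 h. The labels call the libraries biological replicates and do not say whether they came from separate cultures or animals, so p-values measure the spread between these libraries, part of which may be technical.

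Per the submitters' processing notes, reads were trimmed with cutadapt 1.9, checked with FastQC, aligned to GRCm39 with HISAT2 2.2.1 and quantified with StringTie 2.1.6. The annotation version is not given in the sources used here. The deposited table gives FPKM (fragments scaled to transcript length and library size) and a count per gene and library, per the file headers. How the authors made the counts is not given. Their values pile up at multiples of 4 (6687 values of 4 against 3161 of 3 and 2040 of 5), so the deposited counts were treated as estimated counts and not as numbers of reads. They are whole numbers, so rounding altered none of them. The authors' own comparison used DESeq2 with a false discovery rate of 0.05 and a minimum of 1.5-fold, per the labels' protocols, and those thresholds were taken over here.

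Columns were matched to samples by name. The main sheet also holds 12 columns of per-library values (6 libraries, FPKM and count) whose names differ from those matched, and none of them was used in any step. The libraries used are the only ones in 3 of the 4 sheets. Column names alone do not settle which libraries belong to the series, and every value below is that of the library so labelled.

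The table holds 30862 gene rows, of which 2697 were at 0 in all libraries used. GENCODE M39 (GRCm39) held 30610 of the gene IDs, all on the same chromosome, and 12882 of them had the same start and end. Coordinates are those of the deposited table. Gene biotypes and the share of a gene's exon bases that lie inside other genes came from GENCODE M39. Strand use in counting is not given, so reads of overlapping or antisense genes, of ribosomal protein genes and of their pseudogenes cannot be told apart with certainty. Gene Ontology text was not used for 2187 rows.

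Totals ran from 56967176 to 70240738 estimated counts per library. Mitochondrially encoded genes held 2.13% to 2.41% of them, and the 10 most abundant genes 6.55% to 7.32%. No pair of libraries was identical within sampling noise: chi-square per degree of freedom over genes ran from 15.5 to 160. FPKM summed to 274177, 278379 and 283405 in control 1, 2 and 3, and to 284964, 285443 and 290681 in PS-MP 1, 2 and 3. FPKM means thus tend to lie slightly higher with PS-MP than the log2 fold changes, which use TMM scaling, would give.

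Gene tests used edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, quasi-likelihood test, two-sided, treatment as the only term) over all 6 libraries, with Benjamini-Hochberg adjustment over 17186 tested genes. A gene was called changed at an adjusted p under 0.05 and at least 1.5-fold. Standard errors and 95% intervals of log2 fold changes come from the same fit. Gene lists and cell type marker lists were tested with camera in limma 3.58.1 (preset inter-gene correlation of 0.01), again with an estimated correlation, and with fry for direction; 34 lists had tested members, and erythrocyte markers had none (0 tested genes). Camera was also run over 2486 GO and KEGG terms of 10 to 500 tested genes. Tests, gene lists, the first set of alternatives and the rule for named genes were fixed before the data were examined.

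That rule names the 12 genes with the largest and the 12 with the smallest fold change among those called, with libraries that do not overlap and a mean of at least 100 counts in the higher group (none passed). It then takes up to 4 called members per list or, with fewer than 2 called, the 2 members with the highest mean expression, and 17 fixed genes. Fshr and Cyp19a1 are among the fixed genes and were not analysed here. One gene that the rule names is not reported here. Other genes named in the text, such as Hmgcs1, Fdps, Fdft1, Msmo1, Pgk1, Amotl2, Lats2, Lims2, Myh11, Lmod1, Gsta4, Prdx1, Areg, Btc, Cxcl5, Il33, Snhg4 and the interferon-stimulated genes beyond Bst2 and Isg15, were chosen after their values were seen.

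Replicate numbers are shared between the groups. Deviations from the group means, over 9335 genes above 10 CPM (counts scaled to library size), correlated at 0.82, 0.17 and 0.67 between same-numbered control and PS-MP libraries (numbers 1, 2 and 3). Each lay above 0.1, the level used for treating the numbers as pairs. So did control 3 with PS-MP 2 (0.40) and control 2 with PS-MP 3 (0.16), so that level does not mark out pair 2. The other unlike-numbered correlations were negative. Deviations from a group mean sum to 0 within the group, so positive correlations force negative ones, and these are no sign of pairing. By chi-square per degree of freedom, control 3 lay nearer to PS-MP 2 (29.3) than to PS-MP 3 (51.5). Numbers 1 and 2 lay nearest to their own partners (21.3 and 15.5). The first principal component also set the numbers apart. The pairing thus comes from the data, as the labels name no shared culture or day. The fit with the replicate number as a block is given beside a result where it alters the call.

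Simulated counts took the spread of these libraries from the blocked fit, with 50 altered genes per fold drawn from those averaging at least 100 counts. Here a gene counted as called at an adjusted p under 0.05 alone, without the minimum fold. In 16732 tested genes, the fit without the block called 18% of genes altered 1.5-fold, 54% of those altered 2-fold and 82% of those altered 4-fold. With the block these shares were 72%, 94% and 100%. Among unaltered genes 0% were called without and 0.0907% with the block. The simulation gave same-numbered libraries a common mean apart from the altered genes, so the pairing was built in. The gain with the block follows from that setting and does not test the pairing of the real libraries.

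Alternatives were DESeq2 size factors in place of TMM, no filter, a filter of at least 50 counts in at least 3 libraries, DESeq2 1.42.0, limma-voom, removal of mitochondrially encoded genes, the replicate block, no minimum fold and each library left out. Those chosen after seeing the data were counts divided by 4, limma-trend on log2(FPKM + 1) with at least 1 FPKM in at least 3 libraries, the block combined with other tools, and the block with each pair left out. Fits with a single library left out had no block and left 1 library without its same-numbered partner. Differences between the numbers then enter the contrast of PS-MP with control.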

Results

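The question was how polystyrene particles alter the transcriptome of granulosa cells, the somatic cells that surround and support the oocyte, with cytoskeletal and epigenetic genes as the stated interest. RNA was sequenced in 3 libraries from control cells and 3 libraries from cells exposed to 750 µg/mL of 100 nm polystyrene particles (PS-MP) for 24 h. The control libraries held 56967176, 63807940 and 60212563 estimated counts and the PS-MP libraries 70240738, 61307867 and 65714412. Between 11439 and 11608 genes per library reached 1 FPKM.

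In these libraries granulosa markers were low and contractile and matrix genes were high, in both groups. Foxl2, the transcription factor that maintains granulosa identity (chromosome 9, 98837341 to 98840596, GRCm39), was at 0.112 ± 0.0802 FPKM in control and 0.109 ± 0.0357 in PS-MP libraries (SD, n = 3 each, as for all values below). Amh, a hormone of growing follicles, was at 0.218 ± 0.0339 and 0.0883 ± 0.0285 FPKM, and Inha, the inhibin alpha subunit, at 0.932 ± 0.188 and 1.10 ± 0.0961 FPKM. Cyp11a1, which starts steroid synthesis from cholesterol, stayed at or below 0.0360 FPKM in every library and was not tested. The granulosa list did not pass between PS-MP and control (median log2 fold change -0.03, adjusted p = 0.563 by camera). Of its 18 tested members, Amh included, 0 were called changed. Among granulosa list members the highest levels were those of Inhba (122 ± 20.9 and 112 ± 23.0 FPKM) and Gja1 (10.2 ± 0.984 and 11.1 ± 0.795 FPKM). By contrast Acta2, smooth muscle actin (chromosome 19, 34218490 to 34232990), stood at 1851 ± 268 and 1807 ± 369 FPKM. Col1a1, the main fibrillar collagen chain, stood at 691 ± 258 and 618 ± 158 FPKM, and Des, the intermediate filament of muscle cells and pericytes, at 136 ± 30.9 and 119 ± 24.3 FPKM. Of leukocyte markers, Ptprc did not exceed 0.00288 FPKM, whereas Cd68 averaged 2.29 ± 0.640 and 2.54 ± 0.379 FPKM and Lyz2 0.853 ± 0.395 and 0.706 ± 0.414 FPKM. The oocyte factor Gdf9 averaged 0.221 ± 0.0759 and 0.286 ± 0.112 FPKM. With all 6 libraries none of the 6 tested lists of markers of other cell types passed between PS-MP and control without the replicate number as a block; pericyte and smooth muscle markers passed with it, as given with the contractile genes. Ovarian surface epithelium markers depended on single libraries in fits that leave 1 library without its same-numbered partner. Their median was 0.10 with all libraries, 1.02 without control 1 (adjusted p = 0.0122) and 0.49 without PS-MP 3 (0.0387). It was -0.25 without control 3 (0.36) and -0.75 without PS-MP 1 (0.317). Leukocyte markers, with a median of -0.07, passed as lower without PS-MP 3 (adjusted p = 0.0387), where the median of 5 genes was 0.07.

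**Figure D1:**
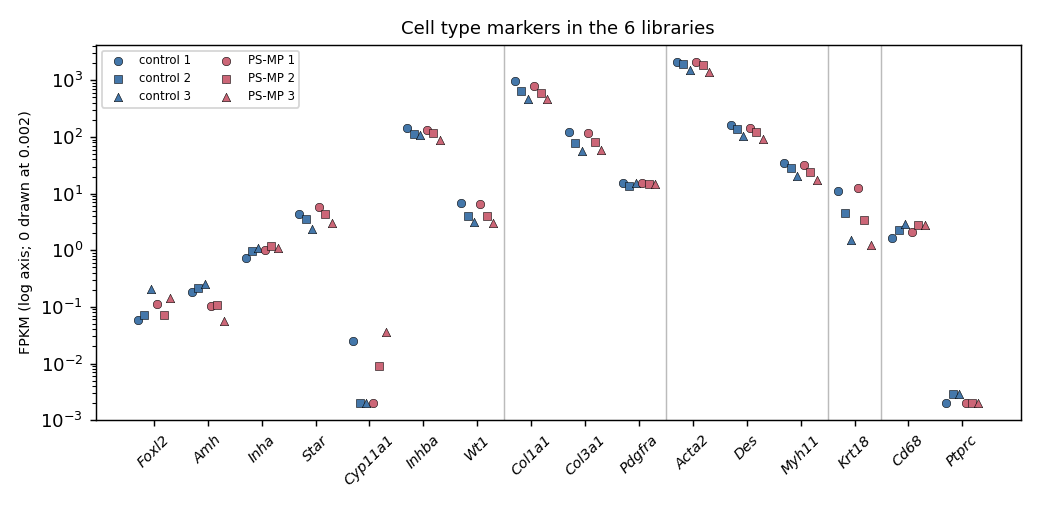
FPKM (log axis) of cell type markers in each of the 6 libraries; colours give the group and shapes the replicate number, and vertical lines part granulosa, stromal, smooth muscle, epithelial and leukocyte markers. Foxl2 averages 0.112 FPKM in control and 0.109 FPKM in PS-MP libraries, while Acta2 averages 1851 FPKM in control and 1807 FPKM in PS-MP libraries.

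No single gene passed the test for an effect of PS-MP. With edgeR's quasi-likelihood test 0 of 17186 genes were called changed, 0 higher and 0 lower, and the lowest adjusted p was 1.00. At an unadjusted p under 0.05 there were 226 genes, 1.32% of those tested. This lies below the share of 0.05 that would pass without any effect. Of the 226 genes, 146 had a positive and 80 a negative log2 fold change. DESeq2 called 1 gene, a row with the symbol Snhg4 that is described with the blocked fit below. By limma-voom and limma-trend on FPKM 0 were called. Among 9335 genes above 10 CPM (counts scaled to library size) the median absolute log2 fold change was 0.06. For 91.7% of these genes the 95% interval lay within 1.5-fold in either direction, and 19 had an estimate of at least 1.5-fold. In 1068 genes (6.21%) the 3 libraries of one group all lay above those of the other. The share that a random order of the libraries gives was not computed, so this number is no sign of an effect by itself.

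With the replicate number as a block, 849 genes (4.94%) had an unadjusted p under 0.05, near the share of 0.05 that would pass without any effect. In that fit edgeR called 1 gene, lower with PS-MP. That gene row carries the symbol Snhg4, otherwise the name of a small nucleolar RNA host gene (ENSMUSG00000117694, chromosome 18, 35686457 to 35711992, GRCm39). It averaged 1.38 ± 0.797 FPKM in control and 0.0915 ± 0.0497 FPKM in PS-MP libraries. Its blocked log2 fold change was -3.72 ± 0.31 (SE; adjusted p = 0.0466, edgeR with Benjamini-Hochberg adjustment). DESeq2 called the same row without the block (-3.82, adjusted p = 1.58e-07) and with it (-3.72, 6.3e-15). Other genes cover 92.3% of its exon bases, so its level is uncertain with either tool. The other row with that symbol (ENSMUSG00000117869), which overlaps it on the same strand, was at 2.29 ± 0.788 and 2.78 ± 0.940 FPKM, with a blocked log2 fold change of 0.26 ± 0.09 (SE).

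Most of the variation followed the replicate number. Over the 9335 genes above 10 CPM, 77.6% of the variance went with the number, 7.83% with treatment and 14.6% with neither. Treatment has 1 degree of freedom and the remainder 2. The treatment share is thus close to the remainder per degree of freedom and is no sign of an effect by itself. Log2 CPM of same-numbered libraries of the 2 groups correlated across genes at 0.994 to 0.995. Libraries of 1 group with other numbers correlated at 0.976 to 0.992.

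**Figure D2:**
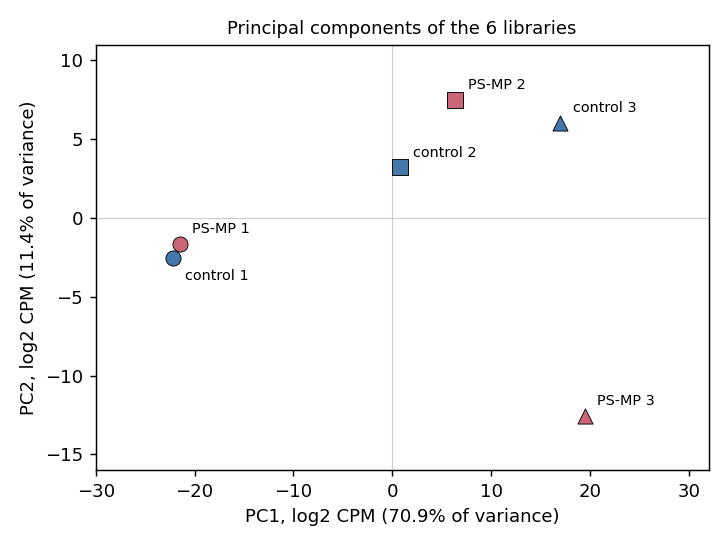
First 2 principal components of log2 CPM over 9335 genes; colours give the group and shapes the replicate number. The first component, with 70.9% of the variance, places both libraries numbered 1 at the left end (-22.2 and -21.5) and both numbered 3 at the right end (17.0 and 19.5).

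Genes of cholesterol synthesis were higher with PS-MP as a group, by a small margin and only at camera's preset correlation. Of 24 tested members 22 had a positive log2 fold change, with a median of 0.15, and the list passed camera (adjusted p = 1.93e-05). The correlation estimated for this list was 0.618, far above the preset of 0.01, and with it the adjusted p was 0.791. Estimates for the lists called without the block ran from 0.00187 for YAP/TAZ and SRF targets to 0.886 for interferon-stimulated genes. The list mean was higher with PS-MP in all 3 pairs, by 0.06, 0.14 and 0.25. Hmgcs1, which makes the first committed intermediate of the mevalonate pathway, averaged 16.2 ± 3.33 FPKM in control and 19.2 ± 3.37 FPKM in PS-MP libraries (log2 fold change 0.23 ± 0.17, SE). Fdps, which makes farnesyl diphosphate, averaged 14.5 ± 2.28 and 17.2 ± 2.21 FPKM (0.23 ± 0.14). Fdft1, the squalene synthase, averaged 10.1 ± 0.737 and 11.8 ± 0.281 FPKM (0.21 ± 0.08), and Msmo1, a sterol oxidase, 8.24 ± 1.53 and 10.2 ± 1.03 FPKM (0.29 ± 0.14). Srebf2, the transcription factor that drives this pathway, had a log2 fold change of -0.00 ± 0.10. No member was called changed, over all genes or adjusted over the list alone (0 members). With the block, 9 members, Hmgcs1, Fdps, Fdft1 and Msmo1 among them, had an adjusted p under 0.05 when adjusted over the list alone. Without control 1 the list median was 0.28 (adjusted p = 9.67e-16), without control 3 it was 0.05 (0.446), and without PS-MP 1 it was 0.06 (0.095), in fits without the block that leave 1 library without its partner. With the block the cholesterol list passed (adjusted p = 4.01e-12, 0.617 with an estimated correlation), and also with pair 1 (4.16e-15), pair 2 (4.06e-08) or pair 3 (0.00036) left out.

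Cytosolic ribosomal protein genes were higher as a group too: 35 of 40 had a positive log2 fold change, with a median of 0.08 (adjusted p = 4.04e-06 by camera, 0.791 with an estimated correlation). Rplp1 averaged 1066 ± 78.0 and 1158 ± 45.5 FPKM and Rpl4 635 ± 2.36 and 679 ± 29.5 FPKM. List means were 0.20, 0.01 and 0.05 higher in pairs 1, 2 and 3, and the list missed the threshold without control 1 (median 0.05, adjusted p = 0.0604) and, with the block, without pair 1 (0.12). DNA replication genes were higher in 32 of 35 members (median 0.08, adjusted p = 0.000137, 0.791 with an estimated correlation). Among them Pcna, the sliding clamp of DNA polymerases, averaged 42.7 ± 2.22 and 49.7 ± 2.62 FPKM (log2 fold change 0.20 ± 0.07) and Rrm2, a ribonucleotide reductase subunit, 52.8 ± 0.521 and 58.8 ± 3.51 FPKM (0.14 ± 0.07). That call was lost without control 2 (median 0.05, adjusted p = 0.0738) and without control 3 (0.05, 0.0559), and the median was 0.16 without control 1 (3.51e-09). It held with the block and any pair left out (highest adjusted p = 0.0246). Glycolysis and hypoxia genes had positive values in 25 of 31 members (median 0.06, adjusted p = 0.00019, 0.42 with an estimated correlation), and this call held with each library left out. Pkm was at 564 ± 24.5 and 588 ± 11.3 FPKM, Aldoa at 523 ± 10.4 and 552 ± 4.53 FPKM, and Pgk1 had a log2 fold change of 0.16 ± 0.07.

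Interferon-stimulated genes passed camera as higher (27 of 29 positive, median 0.27, adjusted p = 0.00426, 0.791 with an estimated correlation), but 1 pair carried the difference. The list mean was 1.15 higher in PS-MP 2 than in control 2, and -0.02 and -0.06 in pairs 1 and 3. Isg15, a ubiquitin-like protein induced by interferon, was at 48.8 FPKM in control 2 and 156 in PS-MP 2, against 6.26 and 8.20 in pair 1 and 240 and 196 in pair 3. Bst2, an antiviral membrane protein, averaged 114 ± 143 and 116 ± 113 FPKM. Without PS-MP 2 the list median was 0.08 (adjusted p = 0.884), without control 1 it was -0.14 (0.322) and without PS-MP 3 it was -0.10 (0.984). The median was 0.11 without control 2 (0.0197), 1.55 without control 3 (5.36e-13) and 0.77 without PS-MP 1 (2.34e-17). The interferon list also missed the threshold with no filter (0.0601), limma-voom (0.0982) and limma-trend on FPKM (0.28).

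**Figure D3:**
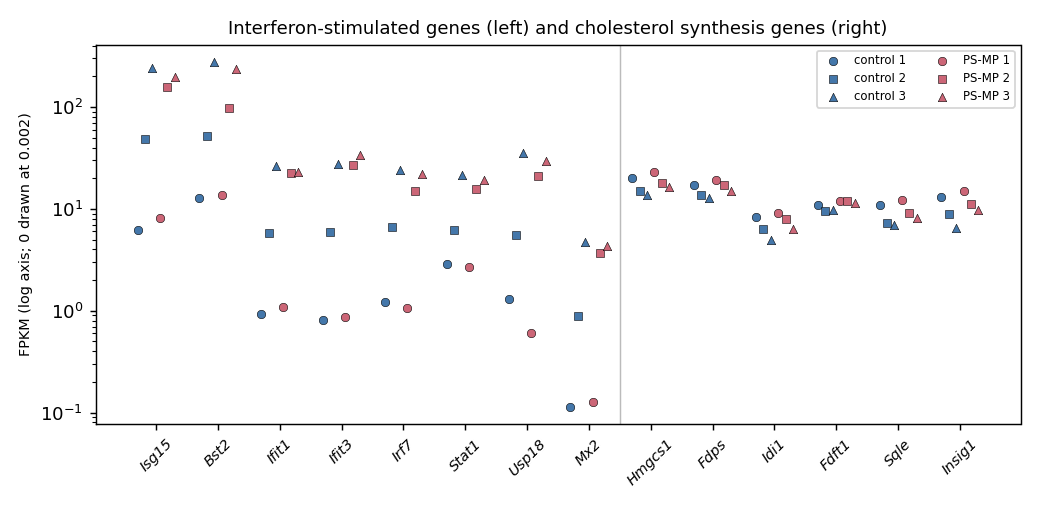
FPKM (log axis) of 8 interferon-stimulated genes and 6 cholesterol synthesis genes in each library; colours give the group and shapes the replicate number. Isg15 spans 6.26 to 240 FPKM among the control libraries, while Hmgcs1 averages 16.2 FPKM in control and 19.2 FPKM in PS-MP libraries.

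Targets of the mechanosensitive factors YAP/TAZ and SRF were lower with PS-MP as a group: 19 of 26 had a negative log2 fold change, with a median of -0.07 (adjusted p = 0.00749 by camera, 0.42 with an estimated correlation), and the list mean was negative in all 3 pairs. Amotl2, a feedback regulator of YAP, averaged 56.8 ± 1.02 and 50.5 ± 1.66 FPKM (log2 fold change -0.19 ± 0.06), and Lats2, a kinase that restrains YAP, had a log2 fold change of -0.15 ± 0.06. The most abundant members, Acta2 and Tagln, had log2 fold changes of -0.06 ± 0.17 and 0.03 ± 0.14. Focal adhesion and integrin genes were lower in 21 of 30 members (median -0.05, adjusted p = 0.0157, 0.791 with an estimated correlation). Lims2, a focal adhesion adaptor, averaged 9.19 ± 0.590 and 7.85 ± 0.376 FPKM, whereas Itgb1 and Itga5 had log2 fold changes of 0.03 ± 0.07 and -0.03 ± 0.17. Without control 1 neither list passed (medians -0.02 and -0.01, adjusted p = 0.316 and 0.899), nor without PS-MP 3 (-0.05 and -0.04, 0.0981 and 0.36), and the focal adhesion list also failed without PS-MP 2 (-0.06, 0.0614). Medians of both lists were -0.12 without control 3 (0.00322 and 0.0003) and -0.12 without PS-MP 1 (0.0125 and 0.0101). With the block and 1 pair left out, YAP/TAZ and SRF targets passed without pair 1 (0.0336), 2 (0.0139) or 3 (0.000176), and focal adhesion genes missed the threshold without pair 1 (0.274).

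Actin cytoskeleton and contractility genes did not pass without the block (28 of 45 negative, median -0.04, adjusted p = 0.119) and were lower with it (adjusted p = 0.00512, 0.617 with an estimated correlation). Pericyte and smooth muscle markers moved in the same direction, with a median of -0.10 and adjusted p of 0.117 without and 0.000706 with the block (0.617 with an estimated correlation). Myh11, smooth muscle myosin, averaged 28.0 ± 6.96 and 24.5 ± 7.12 FPKM, and lay lower with PS-MP in all 3 pairs, as did Des. With the block both passed when adjusted over the list alone (2 members, log2 fold changes -0.22 and -0.21), as did Lmod1, a muscle leiomodin, among the actin genes (1 member, -0.27). Mitosis genes (28 of 33 positive, median 0.05) and nuclear-encoded oxidative phosphorylation genes (24 of 38 positive, median 0.03) did not pass with all 6 libraries in edgeR without the block and passed as higher with it, at adjusted p of 0.00276 and 0.0327 against 0.11 for each without it (0.617 and 0.686 with the block and an estimated correlation). Under other settings without the block, oxidative phosphorylation genes passed with the stricter filter (adjusted p = 0.0287), DESeq2 (0.0411), limma-voom (0.0356), limma-trend on FPKM (0.0064) and counts divided by 4 (0.0289), and mitosis genes with the stricter filter (0.0299) and counts divided by 4 (0.031). Without the block actin genes passed when control 3 (adjusted p = 0.0003) or PS-MP 1 (0.0101) was left out, and their median was 0.02 without control 1 (0.899) or PS-MP 3 (0.748). Without the block, mitosis genes went both ways in fits that leave 1 library without its same-numbered partner. Their median was 0.21 without control 1 (2.2e-09) and 0.18 without PS-MP 3 (5.94e-09), but -0.06 without control 3 (0.137) and -0.10 without PS-MP 1 (0.141). With the block and whole pairs left out their median was 0.07 without pair 1 (0.00402) or pair 3 (0.00101) and 0.02 without pair 2 (0.404). In the same fits actin genes missed the threshold without pair 2 (0.116), smooth muscle markers without pair 1 (0.0802) or 2 (0.0661), and oxidative phosphorylation genes without pair 1 (0.991). Without the block and with 1 library left out, smooth muscle markers passed only without control 3 (median -0.11, 0.0265). Their median was -0.04 without PS-MP 2 (0.558) and -0.05 without control 1 (0.242). Oxidative phosphorylation genes passed only without control 2 (median 0.07, 0.00339), with medians of -0.005 without control 1 (0.899) and 0.006 without PS-MP 2 (0.558). Their list means were 0.14, -0.03 and 0.01 in pairs 1, 2 and 3. Actb, the main cytoplasmic actin, averaged 1715 ± 242 and 1645 ± 101 FPKM (log2 fold change -0.08, 95% interval -0.35 to 0.19). Microtubule genes had a median of 0.04 (adjusted p = 0.185, and 0.0829 with the block). Without the block, leaving out any 1 library gave no call, with medians from 0.001 without control 3 (0.968) to 0.085 without control 2 (0.131). Microtubule genes passed as higher by limma-trend on FPKM (0.0246) and, with the block, by DESeq2 (0.0118), limma-voom (0.0184) and limma-trend (0.041) and without pair 1 (0.0336). Tubb5 was at 497 ± 42.3 and 543 ± 20.7 FPKM (0.11, -0.09 to 0.31) and Tuba1a at 723 ± 43.0 and 812 ± 23.3 FPKM (0.15, -0.02 to 0.32).

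**Figure D4:**
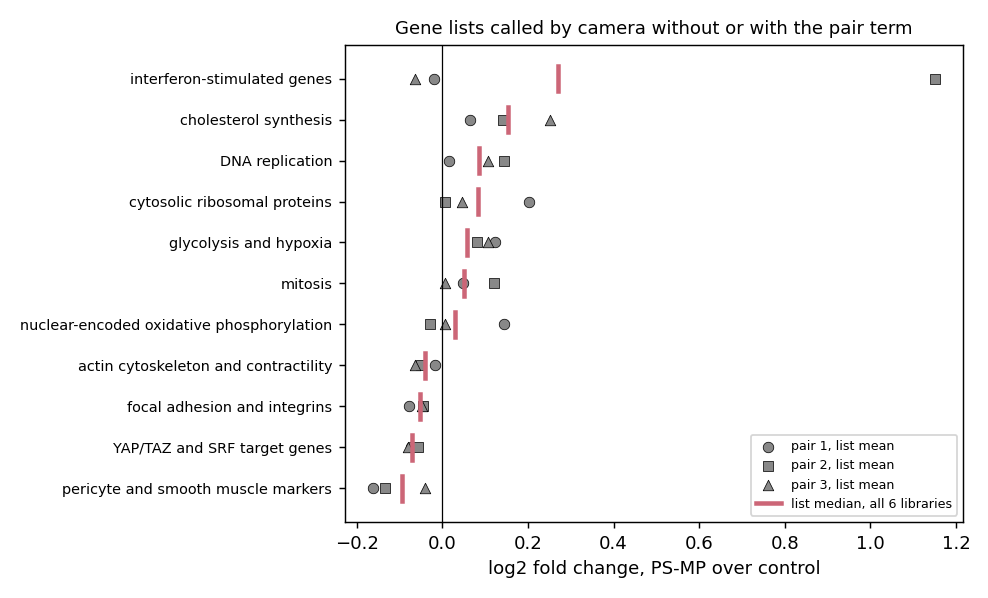
Log2 fold changes (PS-MP over control) of the 11 gene lists that camera called without or with the block; grey symbols give the list mean in each same-numbered pair and red bars the list median over all 6 libraries. Medians run from -0.10 for pericyte and smooth muscle markers to 0.27 for interferon-stimulated genes, for which only pair 2 lies above 0.

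Epigenetic enzymes did not differ detectably with all 6 libraries. The DNA methylation machinery had a median log2 fold change of -0.03 (0 of 20 members called, adjusted p = 0.367 by camera), histone methylation enzymes one of -0.03 (0 of 47, 0.367) and histone acetylation enzymes one of 0.01 (0 of 33, 0.833). Dnmt1, the maintenance methyltransferase, averaged 16.9 ± 1.89 and 17.4 ± 1.09 FPKM (log2 fold change 0.02, 95% interval -0.20 to 0.25). Dnmt3a, a de novo methyltransferase, had 1.57 ± 0.477 and 1.51 ± 0.455 FPKM (-0.07, -0.69 to 0.55). Ezh2, the catalytic subunit of Polycomb complex PRC2, had 7.00 ± 0.738 and 7.34 ± 0.658 FPKM (0.05, -0.20 to 0.29), and Hdac1, a histone deacetylase, 26.2 ± 1.63 and 27.8 ± 0.759 FPKM (0.07, -0.09 to 0.22). The histone methylation list passed as lower when control 3 (median -0.04, adjusted p = 0.0415) or PS-MP 1 (-0.05, 0.0295) was left out, and with the block without pair 3 (-0.04, 0.0418). Its median was -0.06 without control 2 (0.0738) and 0.04 without control 1 (0.242).

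Steroidogenic, stress and death genes did not pass camera as groups either in edgeR with all 6 libraries. Steroidogenesis genes had a median of 0.08 (0 of 14 called, adjusted p = 0.401); Star, which carries cholesterol into mitochondria, averaged 3.43 ± 1.06 and 4.41 ± 1.42 FPKM (log2 fold change 0.34, 95% interval -0.36 to 1.04), with 58.5% of its exon bases inside other genes. With the block and adjusted over the list alone, Star passed in its list (1 member, 0.34), Gsta4 and Prdx1 among the antioxidant genes (0.42 and 0.28), Areg and Btc among the ovulation genes (0.27 and 0.42), and Cxcl5 and Il33 among the inflammatory genes (-0.37 and 0.34). Ovulation and luteinization genes had a median of -0.06 (adjusted p = 0.401) and passed as lower with the stricter filter (0.0154), counts divided by 4 (0.0167) and limma-trend on FPKM (0.0064), with Ptgs2, the inducible prostaglandin synthase, at 484 ± 57.8 and 428 ± 19.3 FPKM. Antioxidant genes had a median of 0.03 (adjusted p = 0.367), and Hmox1, haem oxygenase, averaged 286 ± 122 and 239 ± 63.2 FPKM (-0.27, -1.03 to 0.48). Medians were -0.02 for the unfolded protein response (adjusted p = 0.388), -0.04 for heat shock genes (0.156) and 0.00 for p53 targets (0.706), among which Cdkn1a, a cell cycle inhibitor, had 134 ± 27.2 and 132 ± 25.8 FPKM. Some of these lists passed when 1 library was left out: antioxidant genes without control 3 (median 0.07, adjusted p = 0.0134), heat shock genes without control 3 (-0.06, 0.0415) and without PS-MP 1 (-0.08, 0.0125), and, without PS-MP 1, the unfolded protein response (-0.07, 0.0307) and p53 targets (0.10, 0.0295). With the block, heat shock genes passed by DESeq2 (0.0187) and limma-voom (0.041), the unfolded protein response by DESeq2 (0.0238), and antioxidant (0.0158) and extracellular matrix genes (-0.03, 0.0236) without pair 3. Signalling by TGF-beta, BMP and activin passed as lower with the block by DESeq2 (0.0233) and limma-voom (0.0467), and mitochondrially encoded genes by both tools (0.00835 and 0.041) and without pair 1 (0.0336). Lysosome and autophagy genes, with a median of 0.04 (adjusted p = 0.429), passed as higher without control 3 (0.14, 0.000709) and PS-MP 1 (0.13, 0.00574) and as lower without PS-MP 3 (-0.07, 0.0387). Mki67, a proliferation marker, had a log2 fold change of 0.01 (95% interval -0.45 to 0.48). Extracellular matrix genes had a median of -0.00 (adjusted p = 0.939), with Timp1 at 1460 ± 31.9 and 1553 ± 12.5 FPKM (log2 fold change 0.07, 95% interval -0.07 to 0.21). Left-out libraries turned this list both ways, to 0.13 without control 1 (adjusted p = 0.00433) and -0.13 without control 3 (0.0106). Calls in such fits, for this and the other lists, cannot be told apart from differences between the replicate numbers. In all, camera left 27 of the 34 lists uncalled without the block, with adjusted p from 0.11 to 0.985. The directional test fry called 0 lists without the block (lowest adjusted p = 0.137) and 2 with it, both lower: metallothioneins and zinc transport (6 genes, median -0.05, adjusted p = 0.00358) and cytosolic heat shock (18 genes, 0.04996).

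Of 2486 annotation terms 13 were higher and 0 lower with PS-MP by camera without the block, and 22 higher and 1 lower with it. The 13 terms concerned cytoplasmic translation and the ribosome (79 genes in the former, median 0.06, adjusted p = 0.00308), cholesterol and steroid biosynthesis (20 genes in the cholesterol biosynthetic process, median 0.17, 0.00308), the proteasome core complex (18 genes, median 0.12, 0.0487) and DNA replication (35 genes, median 0.08, 0.0491). With an estimated correlation 0 terms passed in either fit, and 2 terms were called when PS-MP 2 was left out.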

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

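Alternatives other than those fixed in advance were chosen after the result was seen: counts divided by 4, limma-trend on FPKM, the block combined with other tools or with a pair left out, and every alternative for annotation terms. Against 0 changed genes, DESeq2 gave 1, lower. The replicate block gave 1, lower, as did the block on counts divided by 4 and the block without the libraries numbered 1. Each of these calls was the same Snhg4 row. The block in DESeq2 gave 4 (1 higher, 3 lower). The block without the libraries numbered 2 gave 15 (6 higher, 9 lower), and without those numbered 3 it gave 9 (3 higher, 6 lower). Each of these fits rests on the 2 pairs left. Most rows called in them were pseudogenes or had at least 50% of their exon bases inside other genes. The exceptions were Ifi44, Rps27rt, Gm17494 and Rpl17 without number 2, and Gm14308, Gm43766 and Gm55118 without number 3. Leaving out each library gave 0 to 1 changed, 0 to 0 higher and 0 to 1 lower. All other alternatives gave 0, including no minimum fold. Annotation terms called, 13 as reported, numbered 4 without a filter, 20 with DESeq2, 25 with limma-trend on FPKM, 23 with the replicate block, 29 with the block on counts divided by 4, 41 with the block in DESeq2, 37 with the block in limma-voom, 31 with the block without the libraries numbered 3, and 2 to 25 with each library left out. The cause of these differences was not tested. In fits with a single library left out, differences between the replicate numbers enter the contrast of PS-MP with control. With each library left out, list medians ran from -0.14 to 1.55 for interferon-stimulated genes, from -0.13 to 0.13 for extracellular matrix from -0.0726 to 0.14 for lysosome and autophagy genes, from -0.10 to 0.21 for mitosis genes and from -0.75 to 1.02 for ovarian surface epithelium markers, and signs turned in each; the interferon median was -0.0475 with the block without the libraries numbered 2. Of 778 list values under other settings, 678 stayed on the same side of the threshold, 72 passed where the reported test did not, 23 no longer passed, and in 5 the direction of camera turned with a call on either side. The sign of the list median turned in 97 of the 778, in 91 of them without a call in either fit. None of 1609 values of 74 named genes passed the threshold, and 164 had the opposite sign. Beyond 1 gene, 4 lists by camera, 2 by fry for direction, members adjusted over their list alone and the terms, the replicate block altered no other call in edgeR, camera or fry for direction. The mixed test of fry called 0 lists without the block (lowest adjusted p = 0.867) and 5 with it (lowest 0.0384). The block also moved the lists called by camera from 6 higher and 2 lower to 8 and 8 in DESeq2, from 5 and 2 to 8 and 7 in limma-voom, from 6 and 3 to 8 and 4 in limma-trend, and from 7 and 3 to 7 and 4 with counts divided by 4. Alternatives for FPKM alone (quantile scaling, pseudocount of 0.1) were not run, as counts were at hand. The 6 libraries allow 10 splits into groups of 3, too few for a share under 0.05: the real split gave 0 changed genes, 7 lists and 13 terms, and the highest other split 53, 15 and 106. The split with 53 changed genes and 106 terms put both libraries numbered 1 in one group and both numbered 3 in the other, and so many calls point to a structure of the samples. At these depths the spread between libraries, more than counting error, limits the single-gene test.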

Other observations

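The tests on shared sequence and on interferon-stimulated genes, and those on parts of the length and GC check, were chosen after the result was seen. Libraries differed by replicate number far more than by treatment. With the treatment in the fit, 2568 of 17186 genes differed between the numbers (edgeR, adjusted p under 0.05), and 1222 of them differed at least 1.5-fold between numbers 1 and 3, 792 higher and 430 lower in number 3. Interferon-stimulated genes led this contrast: Ifit3b differed by 5.63 on the log2 scale, Ifi44 by 5.45, Isg15 by 4.99 and Irf7 by 4.33. Upk1b, an epithelial membrane protein, went the other way (-2.54) and was at 8.53 FPKM in control 1 and 1.28 in control 3, and at 9.77 and 1.89 in PS-MP 1 and 3. Krt18, an epithelial keratin, was at 12.4, 3.47 and 1.23 FPKM in PS-MP 1, 2 and 3.

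Interferon-stimulated genes differed within both groups, and PS-MP 2 lay above control 2. With the block and pair 2 left out, the list passed camera as lower (median -0.0475, adjusted p = 0.029) and Ifi44 was called lower (-0.72, adjusted p = 0.00839, edgeR). Pair 2 was left out because it carried the difference, so that fit cannot test a rise in every pair. The list means themselves, -0.02, 1.15 and -0.06 in pairs 1, 2 and 3, showed no rise in pairs 1 and 3. With 1 library per group in each pair, whether PS-MP acted on these genes in any pair stays open. Leukocytes were tested in 3 forms against a bound of 1%, each chosen after the values were seen: leukocyte markers summed to 0.498% of the interferon list in control 3, where that list was highest (925 FPKM), to 2.95% in PS-MP 1, where the share was highest, and across the 6 libraries they gained 0.195% of what the list gained (SE 0.0191%, upper 95% bound 0.248%). The last form argues only against RNA held in leukocytes as the whole source of the differences between libraries. Marker levels cannot show whether a few such cells acted on the other cells, so that stays open. The share in PS-MP 1 leaves a part open, and a difference in interferon exposure between preparation days may remain too, as the labels give no date to test it.

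Small shifts of many genes with PS-MP formed the lists that camera called, 11 of 34 with the block at the preset correlation. With an estimated correlation camera called 0 lists in that fit (lowest adjusted p = 0.617). Swapping the control and PS-MP labels within a pair gave 9, 3 and 2 lists, so that the real labels gave the highest count in 1 of 4 arrangements, too few to tell it from chance. Removing a trend with transcript length and GC content, which took 4.51% of the variance of the test statistic, left 10 of the 11 lists past the threshold in the same direction with adjusted p up to 0.00644, which argues against such a trend as the whole cause for those 10. For oxidative phosphorylation, at an adjusted p of 0.0327 in the blocked fit itself, the ranking used for this check gave other values: the mean statistic went from 0.57 to 0.42 and the adjusted p from 0.012 to 0.0626, so length and GC content cannot be told apart from PS-MP there. Whether PS-MP caused the shifts in any of these lists was left open by these 3 pairs.

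The gene rows with the smallest p in the blocked test often shared sequence with other rows. Among the 50 with the smallest p, 28.0% were pseudogenes or had at least 50% of their exon bases inside other genes, against 12.2% of the other 17136 tested rows (Fisher's exact test, two-sided, p = 0.00358). Reads divided unevenly between such rows are thus a candidate explanation for part of them, including Snhg4, Gm29253 (log2 fold change -5.31 with the block, 91.4% of exon bases shared) and the processed pseudogene Gm10123 (1.45). The measure did not mark 36 of the 50, among them Cxcl5, a neutrophil chemokine (-0.37), and Ass1, an enzyme of arginine synthesis (0.31), neither past the adjusted threshold (0.442 and 0.883). It counts only pseudogenes and overlapping exons, so sequence shared between distant rows is missed. The unmarked rows also held Rps27rt (-0.73) and Rpl17 (0.91), rows of ribosomal protein genes, for which shared reads stay possible. Whether PS-MP acts on any of these genes was not tested beyond the fits above.

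Foxl2 at 0.112 FPKM and Acta2 at 1851 FPKM in control libraries describe these libraries as labelled, and PS-MP libraries had similar values. Which cells the cultures held was not tested.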
